A study of Mus musculus with 7 samples.

How the data were processed

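LSK cells, the fraction of mouse bone marrow that lacks lineage markers and carries Sca-1 and Kit and that holds the stem cells and multipotent progenitors of blood, were sorted by flow cytometry from mice aged 7 weeks. The labels describe 4 control libraries, from mice with the Vav1Cre transgene alone, and 3 libraries from Jmjd1c f/f Vav1Cre mice, in which a blood-wide Cre recombinase acts on the floxed gene; these are called control and Jmjd1c here. RNA was extracted with Trizol, amplified with an ultra-low-input SMARTer kit and made into paired-end Illumina libraries, per the labels' protocols. The labels do not say whether each library came from a separate animal, so every p-value measures only the spread between these 7 libraries, which may be technical.

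The deposited table holds a signal per gene, not raw counts, for 39179 Ensembl gene IDs. The submitters' processing notes name Trim Galore 0.2.8, STAR with no version, HTSeq 0.6.1p1, DESeq 1.18.0 and the mouse build mm10; the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Within each deposited column the signal values were whole multiples of a single step, between 0.80 and 1.21 per library, as gene counts divided by a size factor are. Dividing by that step returned whole numbers for 100% of the values above 0, within a tolerance of 0.01 of a read and with a largest distance of 6.09e-06. The recovered reads assigned to genes ranged from 4303712 in control 2 to 6436519 in control 1, and 17538 to 18433 genes had at least 1 read. Gene symbols came from a reference table of IDs and symbols, which matched 37607 of the 39179 IDs. Positions, transcript GC content and length came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and 136 of the tested genes had no entry there.

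The test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1), without further scaling, for the 12813 genes with a value of at least 10 in at least 3 libraries, with 4 control against 3 Jmjd1c libraries in a single fit and no covariate. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Jmjd1c was also tested by a two-sided exact permutation test over the 35 splits of the 7 libraries. Errors beside means are SDs, and errors beside log2 fold changes are standard errors from limma.

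Gene lists were written before the data were examined: 30 lists with 851 entries and 815 distinct symbols, of which 843 entries were found in the table. They cover stem cell and lineage programmes, cell cycle, lysine demethylases and the methylation mark they act on, HoxA and Meis genes, metabolism, stress, and markers of other cell types that a sort can let through. The 29 lists with at least 5 tested members, sex-linked genes excluded, were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Members past the threshold are counted after adjustment over all tested genes and after adjustment over the list alone.

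Genes named in the text follow a rule also fixed before the data were examined, which gave 101 genes. It takes Jmjd1c; the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap and whose mean value is at least 50, leaving out predicted genes and pseudogenes; from each list up to 4 members past the threshold over all genes or over the list alone, or the 2 smallest p-values where none passed; and a few genes in any case, among them Hoxa9, Meis1, Kdm3a, Kdm3b, Kit, Flt3 and Cdkn1c. Some genes that the rule gave are not named in the text. Other genes whose values appear, apart from Xist and the Y-linked genes, are said to have been chosen after their values were seen.

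The steps were tested on simulated counts for the same 12813 genes with the means, library sizes and dispersions of these libraries. Of 100 genes changed 1.5-fold, 35% were called in the right direction, and of 100 genes changed 2-fold, 73% were called. Of the 118 genes called, 8.48% were unchanged ones, and 0 genes were called when nothing was changed. Differences under about 1.5-fold in single genes are thus mostly below what these 7 libraries can resolve. A list moved by 0.3 on the log2 scale was the only one called. Genes were simulated independently of one another, so this does not measure false calls of lists whose genes vary together.

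Alternatives planned before the data were examined were pseudocounts of 0.5 and 10, no filter on low values, a stricter filter of 50, TMM scaling, quantile normalization, array weights, limma without the intensity trend, the replicate number as a block, replicates 1 to 3 alone, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, leaving out each library in turn, an adjusted p threshold of 0.1, and the other set tests. A per-library loess correction for GC content and length (span 0.75), and a fit without control 4 and Jmjd1c 3, were added after the data were seen. Within groups, pairs of libraries differed by 3.24 to 15.3 times the counting noise (chi-square per degree of freedom), so no library was counted as a copy of another. After the called genes were seen, the 148 families of genes that share the opening letters of their symbol and had at least 10 tested members were each tested for an excess of risen genes (one-sided Fisher exact test against all tested genes, Benjamini-Hochberg over the families).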

Results

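Bulk RNA-seq profiles of LSK cells were compared between 4 control and 3 Jmjd1c libraries, to ask how loss of Jmjd1c changes normal blood stem and progenitor cells. JMJD1C is a JmjC-domain protein of the KDM3 family of histone H3 lysine 9 demethylases. Recovered reads in genes were 6436519, 4303712, 4422836 and 6108710 for controls 1 to 4, and 6253793, 4985314 and 4416762 for Jmjd1c 1 to 3. Values are the deposited read counts divided by a size factor per library, called normalized read counts.

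Jmjd1c itself (ENSMUSG00000037876; mm10 chromosome 10, 67096125 to 67256326, plus strand) was 488 ± 30.4 normalized read counts in the control libraries (SD, n = 4) and 264 ± 26.3 in the Jmjd1c libraries (SD, n = 3). Its log2 fold change was -0.89 ± 0.09 (limma, adjusted p = 0.00407), a level 1.85 times lower. The 3 Jmjd1c libraries held 294, 244 and 254, all below the 4 control libraries at 458 to 516, and the exact permutation p of 0.0286 is the smallest that 35 splits allow. The count covers all exons, including those outside the deleted part, so the level that remained does not measure remaining function. Values per gene also cannot show how complete the deletion was. The closest relatives did not pass the threshold: Kdm3a had a log2 fold change of -0.18 (limma, adjusted p = 0.217) and Kdm3b one of 0.16 (adjusted p = 0.354). Of the 21 lysine demethylases tested, Jmjd1c alone fell over all genes, and adjusted over the list alone Phf2 (0.85) and Kdm5c (0.45, and 0.25 without Jmjd1c 3) also rose. Kdm5c, which is X-linked, was 605 in Jmjd1c 3 against 381 and 415 in Jmjd1c 1 and 2. As a list the demethylases did not pass camera (median log2 fold change 0.13, adjusted p = 0.717), and neither did the H3K9 methyltransferases and HP1 proteins (0.07, adjusted p = 0.117, and 0.553 with an estimated correlation). At the preset correlation the latter list did pass camera after the correction for GC content and length (median 0.11, adjusted p = 0.0154) and without Jmjd1c 3 (0.12, adjusted p = 0.0377). Without control 1 its median was 0.135 and it did not pass (camera, adjusted p = 0.105). Of its genes Wiz, a partner of the G9a and GLP enzymes, rose by 0.61 adjusted over the list alone.

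**Figure D1:**
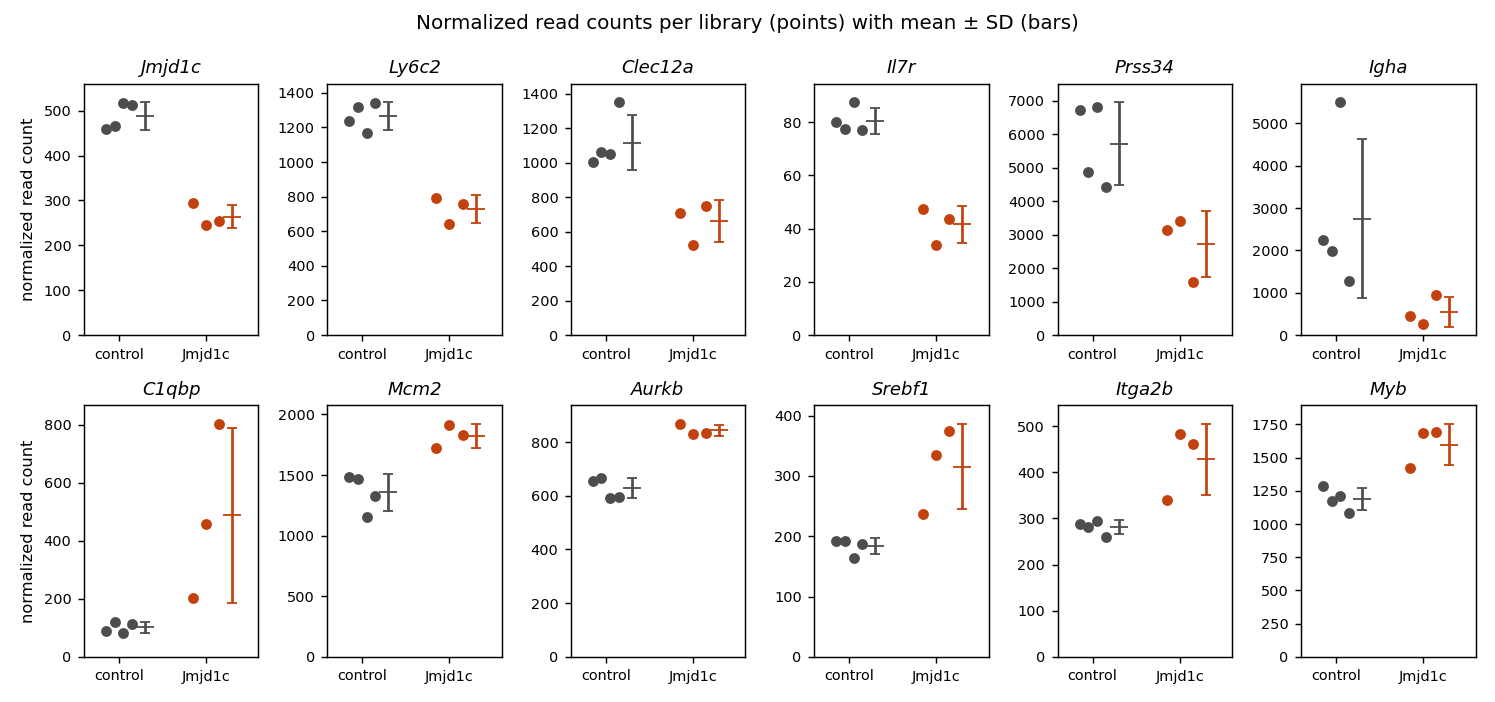
Normalized read counts (vertical axes, from 0) of 12 genes in the 4 control libraries (grey) and the 3 Jmjd1c libraries (orange); each point is 1 library and each bar the mean ± SD. Jmjd1c, Ly6c2, Clec12a, Il7r, Prss34 and Igha lie lower in all 3 Jmjd1c libraries, and the 6 genes of the lower row lie higher in all 3, with C1qbp between 203 and 803.

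Igha, the constant region of immunoglobulin A, fell by 2.29 ± 0.46 on the log2 scale, from 2749 ± 1876 to 553 ± 352. Ccl3, a chemokine of basophils and macrophages, fell by 1.15 ± 0.21, and Prss34, a basophil protease, fell by 1.12 ± 0.23, from 5718 ± 1243 to 2720 ± 978. Outside the written lists, fibronectin (Fn1) fell by 1.11, Wdfy1 by 1.09, the lymphocyte GTPase gene Gimap4 by 1.05 and Rnase4 by 1.02. Il7r, the receptor for the main growth factor of early lymphocytes, fell by 0.95 ± 0.16, from 80.4 ± 4.87 to 41.5 ± 6.78. Ly6c2, a surface antigen of monocytes and their progenitors, fell by 0.80 ± 0.08, from 1267 ± 78.7 to 731 ± 80.8. Adjusted p-values of these genes in limma ran from 0.00407 (Jmjd1c, Ly6c2 and Wdfy1) to 0.041. Immunoglobulin constant regions, Ly6c2 and Ly6c1, and the Gimap genes have close copies, so the counting could lose their reads or assign them to the wrong copy. Rnase4 overlaps Ang.

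Among called genes with a symbol the largest rise was that of C1qbp, a mitochondrial matrix protein, which rose by 2.06 ± 0.35, with 203, 460 and 803 normalized read counts in Jmjd1c 1 to 3 against 82.8 to 122 in control libraries. Med30, a Mediator subunit, rose by 1.76 ± 0.29 and Iscu, the scaffold of iron-sulfur cluster assembly, by 1.58 ± 0.29. Mri1, of the methionine salvage pathway, rose by 1.30. Jak3, the kinase of the common gamma-chain cytokine receptors, rose by 1.28 ± 0.20, from 163 ± 31.3 to 405 ± 129. Marc2 (1.22), Zbtb45 (1.21), Raly (1.12), Eif2b5 (1.09) and Prpsap1 (1.07) rose as well, and the limma adjusted p-values of the 10 genes lay between 0.0292 and 0.0481.

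In all, 231 of 12813 genes passed the threshold in limma, 194 higher and 37 lower in Jmjd1c, so 84.0% of the called genes rose. The risen genes had a median log2 fold change of 0.58 and the fallen genes one of -0.76. In 193 of the 194 risen and all 37 fallen genes the groups did not overlap, as 16.8% of all tested genes did, where chance gives 5.71%. Risen genes were rich in GC: their median transcript GC content was 55.7%, against 50.3% for all tested genes and 50.1% for fallen genes, and the correlation across genes of log2 fold change with GC content was 0.265 (genes are not independent replicates). After a correction for GC content and length, chosen after seeing the data, 98 genes were called, 78 higher and 20 lower. Of 42 named genes called besides Jmjd1c, 22 were still called then. Those that were not are Chil3, Cnn3, Ctsg, Gimap4, Gimap6, Prss34 and Rnase4 among the fallen and Atp5d, Fasn, Foxo3, Itga2b, Marc2, Mcm2, Notch2, Prpsap1, Raly, Srebf1, Tcf3, Tcof1 and Ung among the risen, and all kept their direction. The count rested on single libraries: it was 68 (51 higher, 17 lower) without control 1, 3 (all lower) without each of control 2, control 3 and Jmjd1c 2, 202 (160 higher, 42 lower) without control 4, 624 (511 higher, 113 lower) without Jmjd1c 1 and 9 (1 higher, 8 lower) without Jmjd1c 3. The share of called genes that rose changed with single libraries too, but over 3 or 9 called genes it says little about direction. In those fits many genes still had an unadjusted p under 0.05 in limma. There were 2257 without control 2, 1947 without control 3, 1683 without Jmjd1c 2 and 1750 without Jmjd1c 3, against 2529 with all libraries. All 231 genes kept their direction in each fit that left out a library, but where the groups do not overlap, leaving out a library cannot turn it. edgeR on recovered reads called 233 genes, DESeq2 called 590, and limma without the intensity trend called 0, with 2213 genes at an unadjusted p under 0.05.

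**Figure D2:**
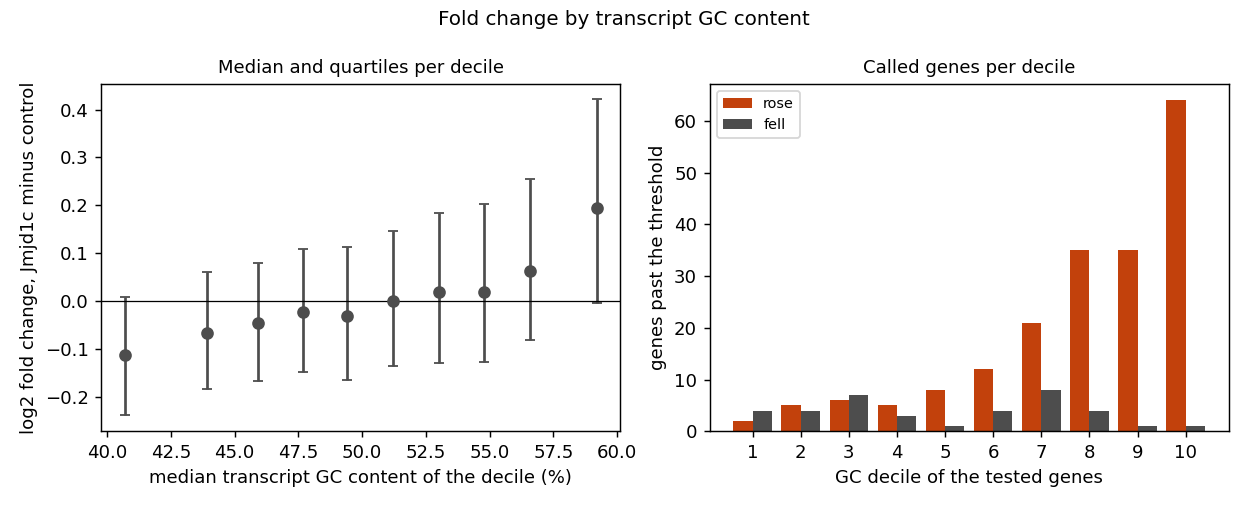
Left, log2 fold change of Jmjd1c against control (vertical axis) by median transcript GC content in percent (horizontal axis) for 10 groups of equal size of the tested genes, as medians with quartiles. Right, the number of risen (orange) and fallen (grey) genes past the threshold in each group. The median runs from -0.11 in the group lowest in GC to 0.20 in the highest, which holds 64 of the risen genes and 1 of the fallen.

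Lists of granulocyte-monocyte and of lymphoid priming genes were lower in camera at its preset correlation alone, as were most lists of mature leukocyte markers. Of 25 granulocyte-monocyte priming genes, 4 fell over all genes and 21 did not pass: Ly6c2 (-0.80), the lectin receptor Clec12a (-0.76), the coagulation factor gene F13a1 (-0.63) and the granule protease Ctsg (-0.46). Adjusted over the list alone, 7 fell and 1 rose. The list was lower in camera (median -0.29, adjusted p = 0.000212), with adjusted p = 0.553 with an estimated correlation and a median of -0.18 without Jmjd1c 2. Of 23 lymphoid priming genes, Il7r, the actin-binding protein gene Cnn3 (-0.76) and Gimap6 (-0.46) fell, Tcf3, which encodes the E2A factors of early B cells, rose by 0.83, and 19 did not pass. Adjusted over the list alone, 11 fell and 1 rose. That list was lower in camera (median -0.25, adjusted p = 0.00256), with adjusted p = 0.553 with an estimated correlation, and Flt3, a receptor of multipotent progenitors, had a log2 fold change of -0.25 ± 0.09 (-0.14 without Jmjd1c 3) that did not pass over all genes (limma, adjusted p = 0.157).

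Of 20 megakaryocyte genes, Itga2b, which encodes CD41, rose by 0.59 ± 0.12, from 281 ± 14.8 to 428 ± 76.4 (0.51 and not called after the correction for GC content and length), and adjusted over the list alone Gata1 (0.46) rose too. The list was higher in camera (median 0.25, adjusted p = 0.0281), with adjusted p = 0.615 with an estimated correlation. Without control 2 its camera adjusted p was 0.0775 and without Jmjd1c 3 it was 0.504, with a median of 0.07, and without control 4 the median was 0.16. The 23 erythroid genes did not pass (median 0.02, camera adjusted p = 0.538), and 1 of them, Gata1, rose adjusted over the list alone.

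Stem cell identity genes did not pass as a list. The 27 HSC identity genes had a median of 0.05 (camera, adjusted p = 0.538) and none was called over all genes. Adjusted over the list alone, Mycn (0.58), the transcription factor Gata2 (0.54) and the channel gene Trpc6 (1.09, and 0.61 without Jmjd1c 3) rose and Sult1a1 fell by 1.01. The 16 HoxA, Meis and Pbx genes had a median of 0.01 (camera, adjusted p = 0.538), which ran from -0.05 to 0.08 without each library. Among them Myb, a regulator of progenitor proliferation, rose by 0.43 ± 0.08, from 1187 ± 84.0 to 1598 ± 155, and Bcl2 rose by 0.33 adjusted over the list alone. Hoxa9 had a log2 fold change of 0.30 ± 0.11 (limma, adjusted p = 0.157) and Meis1 one of 0.00 ± 0.08 (adjusted p = 0.995), whose sign turned with the processing. The receptor Kit (0.15, and 0.05 to 0.22 without each library) and the cell cycle inhibitor Cdkn1c (-0.66, and -0.94 to -0.41 without each library, near 10 normalized read counts) did not pass either.

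Cell cycle and growth lists were higher in camera at its preset correlation, and not with an estimated one. All 30 genes of the S phase and replication list were tested, and 2 rose over all genes: the replicative helicase subunit Mcm2, by 0.43 ± 0.09, from 1358 ± 153 to 1824 ± 97.2, and the uracil glycosylase Ung, by 0.49, though neither was called after the correction for GC content and length (0.35 and 0.40). Adjusted over the list alone Cdt1 (0.46) and Gins2 (0.29) rose too. The list was higher in camera (median 0.16, adjusted p = 3.76e-05), with adjusted p = 0.553 with an estimated correlation. Of 32 genes of G2 and M phase, the mitotic kinase Aurkb (0.43 ± 0.07) and the anaphase activator Cdc20 (0.65 ± 0.12) rose, with Ccna2 (0.46) and Ube2c (0.45) adjusted over the list alone. That list had a median of 0.06 (camera, adjusted p = 0.0129), with adjusted p = 0.615 with an estimated correlation, and without control 4 or Jmjd1c 1 it did not pass (adjusted p = 0.124 and 0.158, medians 0.03 and 0.04), while the median was 0.10 without control 2 and after the correction for GC content and length. Of 40 MYC targets, the pyrimidine synthesis enzyme Cad (0.68) and the nucleolar protein Tcof1 (0.58) rose, with Srm and Mycn among 5 that rose adjusted over the list alone. The median was 0.08 (camera, adjusted p = 0.000212), with adjusted p = 0.553 with an estimated correlation, 0.13 after the correction for GC content and length and 0.05 without Jmjd1c 2. After that correction Tcof1 had 0.38 and was not called. The 21 quiescence genes and cell cycle inhibitors did not pass (median -0.02, camera adjusted p = 0.772), although Foxo3 rose by 0.34 (0.10 and not called after the correction for GC content and length).

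Srebf1, the master regulator of fatty acid synthesis, rose by 0.75 ± 0.14, from 184 ± 13.9 to 316 ± 70.5, and its target Fasn rose by 0.61 ± 0.13, though neither was called after the correction for GC content and length (0.62 and 0.49). Adjusted over the list alone the desaturases Fads1 (0.45) and Fads2 (1.05) rose as well, so 4 of 30 cholesterol and fatty acid genes rose. The list was higher in camera (median 0.17, adjusted p = 0.00383), with adjusted p = 0.595 with an estimated correlation. After the correction for GC content and length the median was 0.09. It was 0.08 without control 2 and 0.06 without Jmjd1c 2, where the list did not pass (camera, adjusted p = 0.0775 and 0.131), and 0.11 without control 4. Fads2 had 0.65 without Jmjd1c 3.

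Lists of mitochondrially encoded and ribosomal protein genes were lower in camera at its preset correlation alone. Over the list alone 7 of 10 mitochondrially encoded genes fell, among them mt-Nd6 (-0.41), mt-Rnr1 (-0.36), mt-Nd5 (-0.30) and mt-Co1 (-0.26), while none passed over all genes. After the correction for GC content and length these 4 genes had log2 fold changes of -0.16, -0.15, -0.12 and -0.12. This list had a median of -0.31 (camera, adjusted p = 1.12e-06), with adjusted p = 0.553 with an estimated correlation, and a median of -0.12 after the correction for GC content and length. Mitochondrial transcripts made up 1.37% to 1.69% of the control values and 1.13% to 1.32% of the Jmjd1c values. The 74 ribosomal protein genes had a narrow shift with a median of -0.13 (camera, adjusted p = 2.19e-11), with adjusted p = 0.553 with an estimated correlation, and none passed alone, with Rps14 at -0.23. Nuclear-encoded genes of oxidative phosphorylation did not pass as a list of 58 (median -0.03, mean 0.00, camera adjusted p = 0.717), but the subunit genes Cox5a and Atp5d each rose by 0.34, Atp5d having 0.19 and no call after that correction. The 27 glycolysis genes did not pass either (median 0.03, and -0.0075 to 0.063 without each library, camera adjusted p = 0.529), with Hk1 (0.55, and 0.36 without Jmjd1c 3), Pdk1 (0.66) and Pfkl (0.27) higher and Ldhb (-0.42) lower adjusted over the list alone.

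**Figure D3:**
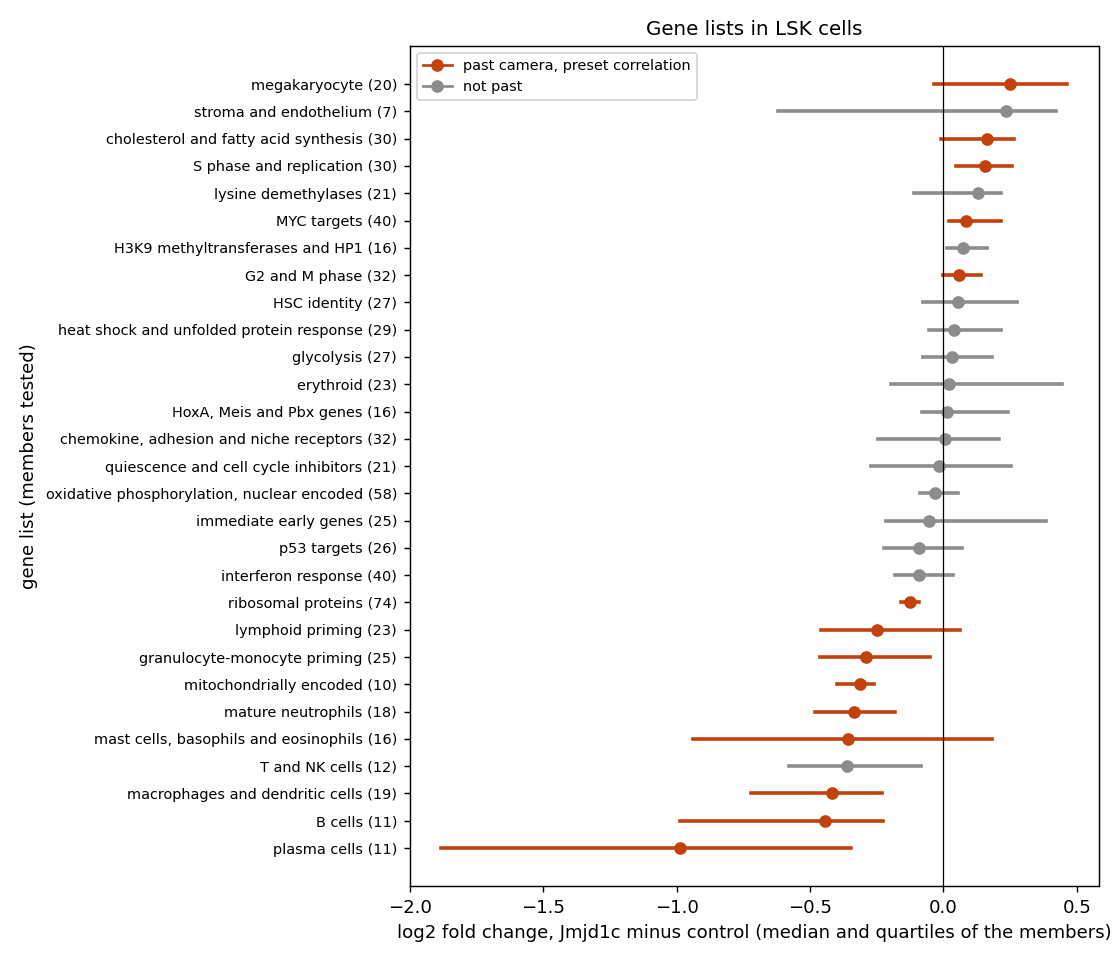
Log2 fold change of Jmjd1c against control (horizontal axis) for the 29 gene lists (vertical axis, with the number of tested members), as the median and quartiles of each list's members. The 14 lists past camera with the preset correlation are orange, 5 of them higher and 9 lower; with an estimated correlation 0 passed.

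Of 6 lists of mature leukocyte markers 5 were lower in camera at its preset correlation, and 0 of them with an estimated one, where 1 of all 29 lists had an unadjusted p under 0.05. In the plasma cell list of 11, Ighg2c fell from 42.3 ± 23.4 to 1.17 ± 1.25 normalized read counts, with 170 reads in the control libraries and 4 in the Jmjd1c libraries, a ratio of 31.3 (95% exact interval 12.0 to 116, counting error only). Adjusted over the list alone 6 fell, with Igkc at -0.99 and Jchain at -0.99, although both lay within the control range in Jmjd1c 3 (7255 and 2591) and had -1.55 and -1.48 without it and -0.58 and -0.67 without Jmjd1c 2. The list was lower in camera (median -0.99, adjusted p = 0.000212), with adjusted p = 0.553 with an estimated correlation and medians of -0.58 without Jmjd1c 2 and -1.48 without Jmjd1c 3. Of 16 genes of mast cells, basophils and eosinophils, 2 fell over all genes, and 8 fell and 1 rose adjusted over the list alone, with Mcpt8 at -1.11 (-0.67 without Jmjd1c 3) and Cyp11a1 at -0.88 (median -0.36, camera adjusted p = 0.00116, adjusted p = 0.553 with an estimated correlation). Of 18 mature neutrophil genes, the secreted protein gene Chil3 fell by 0.59 while the histone-citrullinating enzyme Padi4 rose by 0.90 ± 0.14; Camp (-0.69) and S100a8 (-0.48) were among 5 that fell adjusted over the list alone (median -0.33, or -0.21 without Jmjd1c 2, camera adjusted p = 0.000726, adjusted p = 0.553 with an estimated correlation).

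Of 11 B cell genes, 3 fell adjusted over the list alone, among them Ms4a1 (-2.09) and Cd79a (-1.17), at 21.2 and 16.4 normalized read counts in the control libraries (median -0.44, camera adjusted p = 0.00409, adjusted p = 0.553 with an estimated correlation). None of 19 macrophage and dendritic cell genes passed, and Cd5l (-1.31) and Hmox1 (-0.85, and -0.47 without control 4) had the smallest p-values (median -0.42, camera adjusted p = 0.00459, adjusted p = 0.749 with an estimated correlation). Control 4 stood apart here: the genes of that list summed to 29298 normalized read counts in it, against 8216 to 11474 in controls 1 to 3 and 7336 to 12017 in the Jmjd1c libraries. Without control 4 the B cell list had a median of -0.10 (camera, adjusted p = 0.124) and the macrophage and dendritic cell list one of -0.07 (adjusted p = 0.731), and without Jmjd1c 2 the latter had adjusted p = 0.12. The medians of the 2 lists were -0.71 and -0.68 without control 1 and both -0.69 without Jmjd1c 1. The 12 T and NK cell genes did not pass (median -0.36, camera adjusted p = 0.181), with Cd4 at -0.82 (-0.48 without control 4) and Nkg7 at 0.22 (0.14 to 0.38 without each library). The 7 stromal and endothelial genes tested did not pass (median 0.24, mean -0.05, camera adjusted p = 0.717), although Cxcl12 (-1.16) and Emcn (-0.50) fell adjusted over the list alone.

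**Figure D4:**
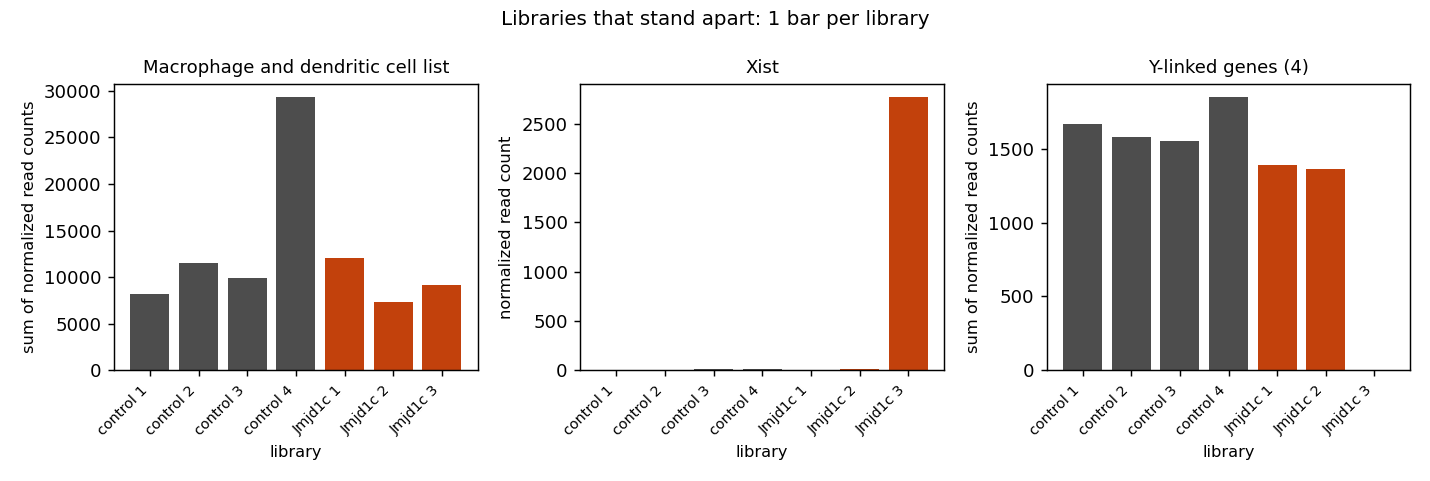
Sums of normalized read counts of the macrophage and dendritic cell list (left), the normalized read count of Xist (middle) and the sum over 4 Y-linked genes (right), 1 bar per library, control in grey and Jmjd1c in orange. Control 4 holds 29298 for the list, and Jmjd1c 3 holds 2767 for Xist and 0 for the Y-linked genes.

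The receptor and stress lists did not pass. Among 32 chemokine, adhesion and niche receptors (median 0.00, mean -0.05, camera adjusted p = 0.772), Notch2 rose by 0.58 ± 0.12, and adjusted over the list alone the integrin gene Itga5 (0.50) and the P-selectin ligand gene Selplg (0.41) rose while the gut-homing receptor gene Ccr9 (-1.63, and -0.82 without Jmjd1c 3) fell. Neither the 40 interferon response genes (median -0.09, camera adjusted p = 0.467, and 0.84 with an estimated correlation), with Tap1 at 0.48 and Oas3 at 0.45, nor the 26 p53 targets (median -0.09, and -0.11 to -0.02 without each library, adjusted p = 0.538), with Cdkn1a at 0.54 and Tnfrsf10b at 0.51, held a gene past the threshold. In camera at its preset correlation the interferon list had a median of -0.17 and adjusted p = 0.00946 without control 1, but -0.003 and adjusted p = 0.432 without control 4. The 25 immediate early genes (median -0.06, mean 0.10, camera adjusted p = 0.784) and 29 heat shock and unfolded protein response genes (median 0.04, and 0.02 to 0.09 without each library, adjusted p = 0.272) each held 1 that rose adjusted over the list alone, Dusp1 (1.36) and Calr (0.26).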

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

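Tests of GC content (on chromosome 10 too), of Jmjd1c 3 alone, of control 4, of mature leukocytes and of genes within 10 Mb of Jmjd1c were chosen only after the results were seen; the split counts and the odds ratio for chromosome 10 before correction were set beforehand. The genes Ctss, Apoe and Epx, named below, were also chosen after their values were seen. Intervals of medians in this part are bootstrap intervals over genes, which vary together, so they do not measure the spread between libraries. Below, the highest or lowest of the 4 control libraries is compared with the other 3, where chance alone sets about 1 in 20 such groups apart, and 5 of the 101 named genes had such a library.

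Control 4 had the outlying sum of macrophage and dendritic cell genes (29298, others 8216 to 11474), Hmox1 (763, others 233 to 287) and Clec12a (1351, others 1003 to 1061). Control 3 had the outlying Jchain (4560, others 1998 to 2417), Ldhb (796, others 558 to 589) and Srebf1 (163, others 188 to 192). Outside the comparison, Xist, which is transcribed from the inactive X chromosome of females, was 2767 normalized read counts (2357 reads) in Jmjd1c 3 and 4.14 to 9.32 in the other libraries, and Ddx3y, Kdm5d, Uty and Eif2s3y had 0 reads in Jmjd1c 3 and 1312 to 2115 elsewhere. The labels give no sex, but by these genes Jmjd1c 3 had a female pattern and every other library a male one. Sex was not a covariate in the fit. Without Jmjd1c 3 the count of called genes was 9, but without each of control 2, control 3 and Jmjd1c 2 it was 3. The drop is thus not particular to Jmjd1c 3. Of the tested genes, 0 of 431 on the X chromosome and 1 of 5 on the Y chromosome were called.

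With all libraries most called genes rose, though not without control 2, control 3, Jmjd1c 2 or Jmjd1c 3, where only 3 or 9 genes were called. Of the 35 splits of the libraries 1, the real one, called as many genes as the 231 found, the highest other split calling 2. At an unadjusted p under 0.05 in limma the real split had 2529 genes and the split that sets controls 2, 3 and 4 apart had 2037. The real split ranked first by both counts, but 1 of 35 is the smallest share these splits allow, so chance in the grouping was not excluded. A smooth trend with GC content and length took little from these folds: the median log2 fold change of the 193 risen genes with a GC value was 0.58 before and 0.52 after the correction (95% bootstrap interval over genes 0.49 to 0.56), with a median standard error of 0.11 in both. After it 76 of the 193 still passed, and why the others did not was not tested. The genes were chosen by large folds, while the median over the GC groups ran only from -0.11 to 0.195. The correction could thus not have taken most of the rise and does not decide whether a bias linked to GC caused it. A set of 591 genes was chosen as higher in Jmjd1c 3 than in controls 1 and 2. Their median difference between Jmjd1c 1 and 2 and controls 3 and 4 was 0.37 (interval 0.34 to 0.40). Jmjd1c 3 alone thus argues poorly as the source of the rise in these genes, which were not chosen among the called ones. Only this division of the libraries was tried. Controls 3 and 4 had lower medians of the risen genes (-0.06 and -0.03) than controls 1 and 2 (0.02 and 0.06), which may enlarge the difference. Loss of Jmjd1c and a difference in RNA quality or amplification between the groups both stay open: the correlation across genes of a library's deviation with GC content was -0.16 to -0.06 in the controls and 0.08, 0.16 and 0.21 in Jmjd1c 1 to 3, whose risen genes had medians of 0.39, 0.64 and 0.73, and the labels give no measure of RNA quality.

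The fallen genes included leukocyte and lineage-priming genes. Macrophages and dendritic cells carried into control 4 argue poorly as the whole source, since over the 116 genes of 7 other leukocyte and priming lists the median was -0.28 without control 4 (interval -0.35 to -0.23) and -0.33 with it, although the B cell list alone lost its call; for the macrophage and dendritic cell list itself that source may be enough, since its members were 1.73 higher in control 4, with Ctss at 4030 and Apoe at 4689, and without control 4 its camera adjusted p was 0.731. A smooth GC and length trend took little from the folds here too: the median over the 37 fallen genes was -0.73 after the correction (interval -0.96 to -0.53) and -0.76 before, with median standard errors of 0.12 and 0.13, and 18 still passed. Their median GC content was 50.1%, against 50.3% for all tested genes, so such a trend had little to remove. Whether the Jmjd1c sorts let through fewer mature leukocytes stays open: 6 of 6 mature leukocyte lists had medians below 0 without control 4, from -0.07 for macrophages and dendritic cells to -1.11 for plasma cells, but all 6 lay below 0 with it too, so this count decides nothing. Padi4 (0.90) and, adjusted over the list alone, the eosinophil gene Epx (0.89) rose. Lineage depletion is meant to remove such cells, yet markers such as Igkc (4852 to 8076) and Prss34 (4421 to 6828) were high in the control libraries. These bulk values cannot tell which cells they came from. Lower expression of priming genes within LSK cells after loss of Jmjd1c stays open beside a smaller share of mature leukocytes.

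Called genes were more frequent on chromosome 10, which carries Jmjd1c: 20 of 604 tested genes there, all higher, against 209 of 12072 on other chromosomes (odds ratio 1.94, 95% interval 1.15 to 3.11, two-sided Fisher exact p = 0.0109, Jmjd1c left out). Chromosome 5 was close, with 23 of 783 called (2.94%, against 3.31% on chromosome 10), and of all called genes 84.0% rose. A passenger region inherited with the floxed allele would put them near Jmjd1c, but within 10 Mb 1 of 102 was called, against 19 of 502 farther away (Fisher exact p = 0.224), too few to decide. GC-rich genes of the chromosome may also contribute, since after the correction the odds ratio was 1.32 (interval 0.47 to 3.01, 6 genes), although the median GC content of tested genes was 50.2% there and 50.3% elsewhere. Both explanations cannot be told apart with these counts.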

How the results depend on the processing

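The GC and length correction and the fit without control 4 and Jmjd1c 3, the libraries that stand apart, were chosen after seeing the data; the other alternatives were planned, and causes were not tested unless named. Against 231 called genes, limma without the intensity trend called 0 (2213 at an unadjusted p under 0.05; edgeR called 233), the replicate block 16, DESeq2 590, the GC and length correction 98, the fit without both libraries 107 (57 higher, 50 lower) and an adjusted p under 0.1, being a looser threshold, 716. Leaving out each library in turn gave 3 to 624 genes, the fewest without control 2, control 3 or Jmjd1c 2. The called genes kept their direction in every fit, 221 of 221 tested with the stricter filter, 230 of 230 after the GC and length correction and 231 of 231 elsewhere. Where the groups do not overlap, leaving out a library could not have turned the direction. The replicate numbers share no deviation pattern (correlations of -0.15, -0.0021 and 0.0174 for the same-numbered pairs), so the block only takes degrees of freedom from the 6 libraries, in which 202 genes were called without it. The Jmjd1c log2 fold change lay between -0.97 and -0.83 without each library, was -0.86 with the replicate block, and at -0.89 lost its call in the fit without the intensity trend (adjusted p = 0.117, range over the alternatives 2.40e-11 to 0.117). Of 42 other named genes called, edgeR kept 41 calls, the GC and length correction 22, the fit without both libraries 25 and the replicate block 8, and leaving out each library kept 2 to 40, with 0 reversed. The groups do not overlap in these genes, so leaving out a library could not have reversed them. Of the 14 lists past camera, 10 kept their call with the replicate block. With an estimated correlation 0 of all lists passed camera (1 at an unadjusted p under 0.05), and 0 passed fry (5 at an unadjusted p under 0.05). Leaving out each library gave 11 to 15 lists past camera, of which 11 to 14 were among the 14. Reversals were among results that did not pass. Meis1 was 0.0402 with quantile normalization, 0.0475 after the GC and length correction and -0.0568 to 0.0433 without each library. The set test's direction turned for 9 lists, whose medians, which need not turn with it, were: HSC identity -0.00438 with the replicate block or replicates 1 to 3 alone, -0.0762 without both libraries and -0.00438 to 0.117 without each; erythroid -0.0238 to 0.245 without each; quiescence 0.0477 with the block or replicates 1 to 3 alone, -0.0158 in fry and -0.101 to 0.0477 without each; lysine demethylases 0.00442 with the stricter filter, -0.0271 without both and -0.0255 to 0.16 without each. The others were the interferon response, -0.00299 with the block or replicates 1 to 3 alone, 0.0175 without both and -0.167 to -0.00299 without each; immediate early genes, -0.0585 with the stricter filter, -0.068 after the GC and length correction and -0.0966 to 0.00867 without each; and oxidative phosphorylation, 0.0114 after that correction and -0.0568 to -0.00256 without each. Chemokine, adhesion and niche receptors had 0.0396 after that correction, -0.0489 without both and -0.0615 to 0.0204 without each, and stroma and endothelium 0.287 with the stricter filter, 0.339 without both and 0.0319 to 0.351 without each. Depth limits genes near 10 normalized read counts, such as Cdkn1c and Ms4a1, whose folds rest on few reads.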

Other observations

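The search through gene families and all genes named in this part were chosen only after the results were seen; the count of splits was set beforehand. Among 148 families of genes that share the opening letters of their symbol and had at least 10 tested members, 1 passed the adjusted threshold for an excess of risen genes, the splicing factors whose symbols open with Sf, at 4 of 10 (one-sided Fisher exact test, adjusted p = 0.00147 over the families). Sf3a2 rose by 0.92 ± 0.17, from 221 ± 31.2 to 429 ± 125 normalized read counts, Sf3b4 by 0.69 ± 0.11, Sf1, which recognises the branch point, by 0.63 ± 0.11 and Sf3a1 by 0.35 ± 0.07. The rest of the family did not pass, with Sf3b1 at -0.10 and Sf3a3 at -0.03, so its median was 0.07. After the correction for GC content and length 3 of the 10 were called as risen. The calls rested on single libraries: limma called 2 of the 10 without control 1, 3 without control 4, 4 without Jmjd1c 1 and 0 without each of control 2, control 3, Jmjd1c 2 and Jmjd1c 3. In the fits with 0, the risen genes over all tested genes were 0 without control 2, control 3 or Jmjd1c 2 and 1 without Jmjd1c 3, so those fits cannot test the excess. In each of them 4 of the 10 were higher at an unadjusted p under 0.05 (edgeR and DESeq2 were not run on these). Mediator subunits (4 of 30, with Med30 at 1.76, Med25, Med16 at 0.67 and Med15 at 0.39) and translation initiation factors (5 of 53, with Eif5 at 0.69) did not pass after adjustment (adjusted p = 0.0594 for both). Nor did other splicing families in the same exact test, with 2 of 11 Srsf genes risen (median -0.10, adjusted p = 0.424) and 0 of 13 Prpf genes (median -0.03, unadjusted and adjusted p = 1).

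Among the risen genes were also 3 subunits of the SWI/SNF chromatin remodelling complex, chosen after their values were seen and not tested as a group: Smarcc2 (0.70 ± 0.14), the ATPase Smarca4 (0.62 ± 0.14) and its alternative Smarca2 (0.51 ± 0.10). Other subunits did not pass, with Smarcc1 at 0.42 (limma, adjusted p = 0.0538), Smarcb1 at 0.14 and Smarcd2 at -0.21. Without control 2, control 3 or Jmjd1c 2, 0 genes of any kind were called as higher, so these 3 calls were lost there too.

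The number of lists past camera was no larger than regrouping can give. The real split gave 14 lists, and 4 of the 35 splits gave as many, the real one included. Every other split gave lists too, from 1 to 16, so chance in the grouping could not be excluded for the list count. A list past camera at the preset correlation thus does not by itself mark the real grouping.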
